A study of Mus musculus with 20 samples.

How the data were processed

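C2C12 is an established line of mouse myoblasts, muscle precursor cells that fuse into multinucleated myotubes when serum is withdrawn. Per the series' design text, myotubes were differentiated for 96 h and then given H2O2 at 0, 1, 10, 100 or 1000 µM for 2 h in medium with 0.5% horse serum. Total RNA of each sample was hybridised to an Affymetrix Mouse Genome 430A array, a chip of short oligonucleotide probe sets. There were 20 arrays, 4 per dose. Groups were taken from the sample titles. The unit in 1 title of the lowest dose is misspelt and was read as µM. A further title, of a 10 µM array, has no replicate number; that array is called 10 µM replicate 1 here and was left out of the fits with replicate numbers as a block. Because its values grouped with those of the 4 arrays numbered 1, it was placed with them as a batch. The design text speaks of independent replicates, but nothing states that they were separate cultures, so p-values here measure only the spread between these samples, which may be technical.

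The deposited intensity values are linear probe-set signals from Affymetrix Microarray Suite 5.0, per the design text and the submitters' processing notes. Each array's 2% trimmed mean of the deposited signals was 500.1 to 500.2, so the authors' values carry a global scaling to a common trimmed mean. Detection and difference calls of that software were not used here. The median deposited signal of an array ran from 150.9 to 185.1 and the highest from 11650 to 21260. With arrays there is no read depth; the 4 arrays per dose limit the precision. The label field names a pair of dyes although the design text describes a single streptavidin-bound stain, and each array was treated as 1 channel.

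From these values, the remaining small differences in trimmed mean were removed, values were floored at 1, and log2 was taken. Of 22690 probe sets, 64 Affymetrix controls were left out. A probe set was tested if it reached its array's 40th percentile on at least 4 of the 20 arrays, which left 14379 tested and 8247 filtered out. The floor and filter mean that changes of dim probe sets are less exact than those of bright ones. limma 3.58.1 in R 4.3.3 fitted all 5 groups together (lmFit, then eBayes with an intensity trend; 15 residual and 5.33 prior degrees of freedom). Benjamini-Hochberg adjustment was made within each comparison over all tested probe sets, and a change is called, and described as a rise or a fall, at an adjusted p under 0.05. All adjusted p-values of single genes below are limma's, two-sided, with n = 4 arrays per group, and changes are given as log2 differences with their standard errors (SE).

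Gene symbols came from the platform annotation, which can be old, checked by Entrez identifier against a RefSeq table of assembly GRCm38.p6; 0 symbols changed. Of all probe sets, 20393 had exactly 1 symbol, 691 had several and 1606 had none. Probe sets with several or none stay unnamed here. No build is named for the array's own annotation, so no coordinates are given. The tested probe sets with 1 symbol numbered 13271 and covered 8159 genes, 3300 of them with several tested probe sets. A gene is represented by its probe set of highest mean signal, and disagreement among its other probe sets is stated where a gene is named. Counts of genes given beside counts of probe sets are different: they take every gene with at least 1 called probe set in that direction. List calls that arose without 1 array or under another scaling were tested by camera alone.

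Each H2O2 dose was compared with the untreated group, neighbouring doses were compared with each other, a linear trend over dose rank (weights -2, -1, 0, 1 and 2) was fitted, and a moderated F-test asked for any change over the 5 doses. Array measures were compared by exact permutation tests over 70 assignments, two-sided, which cannot go below p = 0.0286.

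Before the data were examined, the samples' groups, the tests, the gene lists, the rule for naming genes and most alternatives were fixed. The 32 gene lists were targets of NRF2, of p53, of ATF4 (amino-acid response), of NF-kB (with cytokines), of hypoxia, of Notch and of TGF-beta and BMP; antioxidant enzymes; metal-responsive genes; heat shock proteins; endoplasmic reticulum chaperones; immediate early genes; MAPK phosphatases and feedback inhibitors; SOCS and STAT genes; contractile genes; myogenic regulators; atrophy genes; proteasome subunits; oxidative phosphorylation subunits; glycolysis; cholesterol synthesis; DNA repair; apoptosis regulators; ribosome biogenesis; cytosolic ribosomal proteins; zinc-finger and transcriptional repressors with short-lived mRNA; and histone genes. Markers of other cells that such cultures could hold were cell cycle genes (cycling undifferentiated cells), fibroblast and matrix genes, quiescent reserve and satellite cell genes, adipocyte, bone and cartilage genes, and leukocyte genes. The list called Notch targets here also holds receptors (Notch1, Notch2, Notch3), ligands (Jag1, Dll1) and the modifier Lfng. Its calls are therefore not calls of targets alone. Some genes stand on several lists, so list calls are not separate results. Examples are Ddit4 (p53 and hypoxia), Btg2 (p53 and immediate early), Atf3 (ATF4 and immediate early), Sesn2 (p53 and ATF4) and Slc2a1 (glycolysis and hypoxia). Lists with at least 5 measured genes were tested, 31 of 32, with limma's camera at its preset inter-gene correlation of 0.01, which asks whether a list moved relative to all other genes. The calls were repeated with a correlation estimated per list and with fry, which asks whether a list's genes moved, on balance, together. Changed members were counted both after adjustment over all tested probe sets and after adjustment over the list alone. The matching of listed names to symbols was corrected after the results were seen: 5 members that had entered through outdated synonyms, 4 of them measured, were taken out, and no list call changed in any comparison.

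Genes were named by a fixed rule. For each dose against 0 µM and for 1000 against 100 µM, these were the 12 largest rises and the 12 largest falls among called genes whose 4 arrays of one group all lay above the 4 of the other, passing over RIKEN and clone names. From each list, up to 4 members of smallest p at 100 and 1000 µM were added, and 5 genes each way for the trend.

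Because replicate numbers recur across doses, a fit with the number as a block was planned beside the main one. Same-numbered arrays deviated together from their group means in every pair (r above 0.1) for 1, 100 and 1000 µM against 0 µM, for 100 against 10 µM (3 pairs) and for 1000 against 100 µM, with r of 0.105 to 0.261 for numbers 2 to 4 and 0.463 to 0.513 for number 1; they did not in every pair for 10 against 0 µM or 10 against 1 µM. The 5 arrays numbered 1, the unnumbered 10 µM array included, deviated together with a mean r of 0.518, whereas in replicates 2 to 4 the mean r was 0.152 for the same and 0.173 for a different number. Centred on group means of their own, replicates 2 to 4 gave a mean r of -0.02 for the same and 0.01 for a different number. The 5 arrays numbered 1 were therefore also treated as a batch. This was done in a fit with a batch term and in a fit to replicates 2 to 4 alone, both chosen after seeing the data.

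The other settings fixed beforehand were the values as deposited, median centring, quantile normalization, 16 or 64 added before log2, no filter, a filter on mean signal, no intensity trend, array weights, only the 2 groups compared, the mean of a gene's probe sets, a minimum change of 1.75-fold, each array left out in turn, controls split between comparisons, and a crossed rule after the design text (all 16 pairs of a treated and an untreated array in 1 direction, with a change above 1.75-fold). Centring on the median of the tested probe sets was added after seeing the data.

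The code was tested on simulated data built on the 14379 probe sets of the comparison of 1000 with 0 µM, in 5 runs with 200 changed probe sets each. It recovered 50% of 1.5-fold, 83.6% of 2-fold and 96.8% of 4-fold rises, with 1.6 false calls per run, and called 0 of 100 unchanged lists. The simulated probe sets varied independently and the unchanged lists were drawn at random. The 0 of 100 therefore says little about real lists, whose genes vary together. The fit with the replicate block recovered 69.2% of 1.5-fold changes there, with 10.4 false calls per run. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.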

Results

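The series measured mRNA levels in C2C12 myotubes, the multinucleated cells that this mouse muscle line forms in culture, after 2 h with H2O2. There were 5 groups of 4 arrays, at 0, 1, 10, 100 and 1000 µM. H2O2 is a diffusible oxidant, and per the design text each dose was set against the untreated myotubes. Correlations between arrays over the tested probe sets lay between 0.9335 and 0.9902, and 0 pairs of arrays held identical values.

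The arrays differed in ways that dose did not set. The first principal component, 28.2% of the variance, separated the 5 arrays numbered 1 (scores from 27.62 to 42.47) from the other 15 (from -16.08 to -6.22), and the second, 15.9%, set the arrays at 100 µM (2.30 to 3.22) and 1000 µM (23.81 to 28.90) apart from the other 3 doses, which overlapped (-16.90 to -0.30). Because each dose has 1 of these 5 arrays, the split is balanced over the doses. Counts, list calls and losses of named genes that changed within replicates 2 to 4 are given below. Fits that leave out 1 of these 5 arrays lose that balance and had no batch term. A call that arose or ended in such a fit can therefore come from the batch rather than from dose. At 1000 µM the median log2 signal over all probe sets lay lower than in untreated arrays by -0.203 (exact permutation test, p = 0.0286, the smallest possible, n = 4; adjusted p = 0.196 over 16 tests of array measures). Ratios of 3' to 5' probe sets of Gapdh and beta-actin, a sign of RNA integrity, differed from the untreated group by at most 0.0803 on the log2 scale at any dose.

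**Figure D1:**
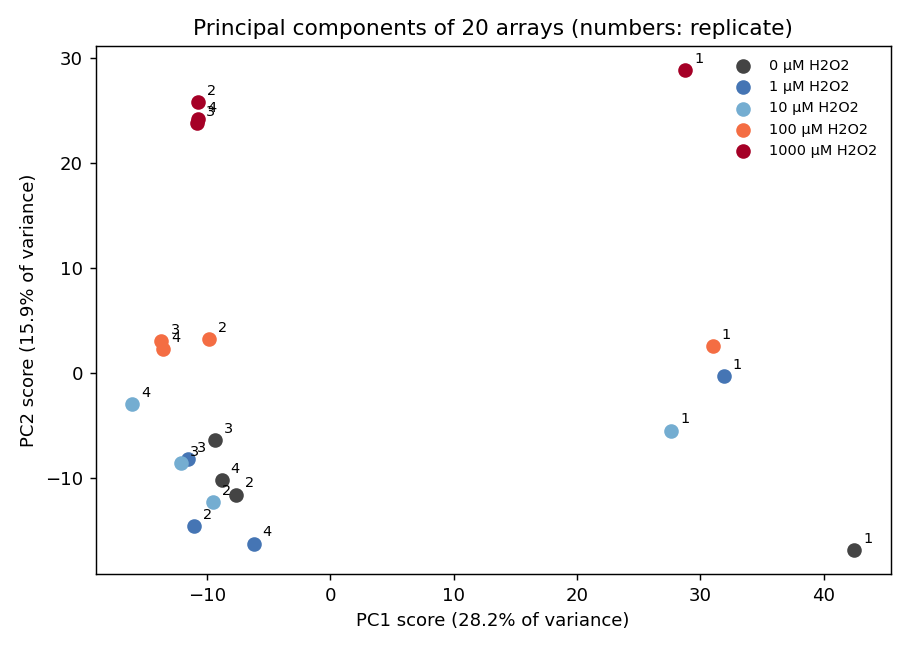
The 20 arrays on the first (28.2% of the variance) and second (15.9%) principal components of log2 signal, with 1 point per array, coloured by H2O2 dose and marked with its replicate number. The 5 arrays numbered 1, the unnumbered 10 µM array included, lie at 27.62 to 42.47 on the horizontal axis and the other 15 at -16.08 to -6.22.

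At 1 and 10 µM hardly any gene passed the test. Hes1, a repressor driven by Notch signalling, fell by 0.61 (SE 0.09, adjusted p = 0.0155, n = 4) at 10 µM, the single call at that dose. The call did not hold without untreated replicates 2 (adjusted p = 0.146), 3 (0.0702) or 4 (0.124), nor without 10 µM replicates 1 (0.0644), 2 (0.0524), 3 (0.0661) or 4 (0.105), or with centring on the median of all (0.254) or of tested probe sets (0.0562). At 1 µM, limma called 0 of 14379 probe sets, with 960 at an unadjusted p under 0.05. The fit with array weights called 49, the batch term 16, replicates 2 to 4 alone 107, the crossed rule 11, and leaving out 1 µM replicate 1 or 3 gave 1 each. At 10 µM the unadjusted count was 717. The replicate block gave 2 calls there, replicates 2 to 4 gave 4 and array weights 79. Between 1 and 10 µM limma called 0 probe sets, and all 14 alternatives also gave 0, with 477 at an unadjusted p under 0.05. No list passed between these doses, but NRF2 targets did with the replicate block (camera adjusted p = 0.0168, against 0.207) and within replicates 2 to 4 (0.0314), where atrophy genes (0.0431) and oxidative phosphorylation (0.0347) passed too. With an estimated correlation 0 of these passed (NRF2 targets 0.425 with the block; 0.16, 0.191 and 0.748 within replicates 2 to 4).

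Lists of abundant transcripts lay higher at these low doses by small amounts, although 0 of their members passed singly over all genes. At 1 µM, camera placed cytosolic ribosomal proteins (median 0.16, adjusted p = 4.74e-08), oxidative phosphorylation subunits (0.09, 6.8e-07) and proteasome subunits (0.10, 3.71e-05) above other genes. It also placed higher contractile genes (0.07, 0.000544), fibroblast and matrix genes (0.13, 0.00165), cell cycle genes (0.07, 0.00225) and glycolysis (0.07, 0.00447), and it placed p53 targets below (-0.10, 0.028). Adjusted over the list alone, 3 p53 targets fell, 2 glycolysis genes rose and 0 members of the other 6 lists changed. With an estimated correlation 0 of these 8 lists passed (adjusted p = 0.247, and 0.515 for fibroblast genes), and after quantile normalization the ribosomal and fibroblast medians turned to -0.004 and -0.01, and only cell cycle genes and p53 targets still passed camera. Calls ended without 1 µM replicate 1 for contractile (0.237), cell cycle (0.0732) and p53 (0.0853) lists, without untreated replicate 1 for fibroblast genes (0.414), without untreated replicates 2 (0.0652) or 4 (0.142) for p53 targets, and without 1 µM replicate 2 for glycolysis (0.0847). Within replicates 2 to 4 the contractile (0.334) and proteasome (0.269, median 0.04) calls ended, and NF-kB targets (0.00886) and immediate early genes (0.0425) passed downward by camera, though not with an estimated correlation (0.378 for both). NF-kB targets, not called in the fit to all arrays (0.0678), passed downward with the replicate block (0.0492, but 0.328 with an estimated correlation), under median centring (0.0217) and without untreated replicate 1 (0.0108) or 1 µM replicate 3 (0.0155). Other calls that arose were those of myogenic regulators without untreated replicate 1 (0.0376), Notch targets without 1 µM replicate 2 (0.0492) and ribosome biogenesis without untreated replicate 1 (0.00675) or 1 µM replicates 2 (0.0408) or 4 (0.00833).

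At 10 µM the lists placed higher were oxidative phosphorylation (median 0.10, adjusted p = 7.01e-11), ribosomal proteins (0.15, 2.59e-08), proteasome (0.09, 8.24e-08), cell cycle (0.08, 2.28e-06), contractile (0.08, 2.53e-05), ribosome biogenesis (0.10, 8.69e-05), fibroblast (0.09, 0.0135) and heat shock genes (0.05, 0.0159). Notch targets lay lower (median -0.09) at an adjusted p printed as 0.05, on the edge of the threshold. Their median turned to 0.01 with median centring, and the p was 0.113 with the replicate block. Cholesterol synthesis passed there instead (0.0234, against 0.0579), but not with an estimated correlation (0.118). Again 0 of the 9 lists passed with an estimated correlation (adjusted p from 0.112 to 0.515), and quantile normalization turned the contractile median to -0.003 and the fibroblast median to -0.013. After it ribosomal, oxidative phosphorylation, proteasome, contractile, fibroblast, heat shock and Notch lists (0.116 to 0.921) no longer passed, nor did fibroblast genes under median centring (0.0753). Adjusted over the list alone, Hes1 fell and 0 other members of the 9 lists changed. Within replicates 2 to 4 the heat shock (0.058) and Notch (0.058) calls ended, ribosome biogenesis also passed with an estimated correlation (0.03), and NRF2 targets (0.0114), antioxidant enzymes (0.0388) and cholesterol synthesis (0.0351) passed upward and immediate early genes (0.0063) and NF-kB targets (0.0351) downward. These last 5 passed camera alone (0.15 with an estimated correlation, and 0.291 for NF-kB targets). Without 10 µM replicate 4 the ribosomal (0.0618), heat shock (0.0618), fibroblast (0.77) and Notch (0.0618) calls ended and 5 lists were left. Other calls ended without untreated replicates 1 (fibroblast, 0.817), 2 (Notch, 0.117), 3 (Notch, 0.176) or 4 (heat shock, 0.0616) and without 10 µM replicate 1 (heat shock 0.0636, ribosome biogenesis 0.0636, Notch 0.186). Calls that arose were immediate early (0.0262) and DNA repair genes (0.022) without untreated replicate 1, cholesterol synthesis without untreated replicate 4 (0.0487), and antioxidant (0.0212), immediate early (0.0425), atrophy (0.0414) and cholesterol genes (0.0281) without 10 µM replicate 1.

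At 100 µM, targets of NRF2, of p53 and of ATF4 (amino-acid response) rose. Changes are log2 differences from untreated myotubes ± SE. The largest rise was that of Slc19a2, a thiamine transporter (2.15 ± 0.15, adjusted p = 1.27e-08), followed by Atf3, a stress-induced transcription factor (1.98 ± 0.45, 0.0247), and Hmox1, haem oxygenase 1 (1.96 ± 0.13, 6.15e-09). Osgin1, an oxidative stress-induced growth inhibitor, rose by 1.93 ± 0.24 and Srxn1, the sulfiredoxin that restores oxidised peroxiredoxins, by 1.30 ± 0.15, the latter with 3 of its 4 probe sets in that direction. Of p53 targets, Trp53inp1 rose by 1.69 ± 0.13, Sesn2, a stress-responsive inhibitor of mTOR signalling, by 1.63 ± 0.21, and Mdm2, the ubiquitin ligase of p53, by 1.33 ± 0.13. The chemokine Ccl2 rose by 1.84 ± 0.22, the forkhead factor Foxq1 by 1.60 ± 0.23, Rnf225 by 1.27 ± 0.26 and Ddit4l, a relative of the mTOR inhibitor Ddit4, by 1.63 ± 0.38. Ddit4l and Rnf225 lay under the filter level on all 4 untreated arrays and Atf3 and Ccl2 on all but 1, so the sizes of these 4 rises, and their ranks, are inexact. Adjusted p of these 12 genes lay between 6.15e-09 and 0.0329. Atf3 was not called without untreated replicates 3 (0.0869) or 4 (0.094) or 100 µM replicates 1 (0.111), 2 (0.0679) or 3 (0.0604), nor Ddit4l without any 1 of the 8 arrays except untreated replicate 1 (0.0586 to 0.135).

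Falls at 100 µM were fewer than rises in the fit to all arrays. Spry1, a feedback inhibitor of growth factor signalling, fell by 0.97 ± 0.10 (adjusted p = 7.46e-06), the LIM-domain protein Ajuba by 0.80 ± 0.11 (0.000262), Myod1, a master regulator of muscle differentiation, by 0.71 ± 0.10 (0.000371). Aspm, a spindle protein, fell by 0.60 ± 0.09 (0.000613), Taf4, a subunit of the basal transcription factor TFIID, by 0.64 ± 0.12 (0.00434), Ect2, a regulator of cytokinesis, by 0.66 ± 0.12 (0.00625), and Pnrc2, a nuclear receptor coactivator, by 0.63 ± 0.12 (0.0101; 0.0595 with median centring). The largest fall, that of Zap70, a kinase known from T cells (-2.23 ± 0.46, 0.0131), was seen in 1 of its 2 probe sets and ended without 100 µM replicates 3 (0.0535) or 4 (0.0618). Kif18a, a mitotic kinesin (-0.97 ± 0.21, 0.0212), lay under the filter level on all but 1 of the arrays of 100 µM and was not called without untreated replicates 2 (0.0558) or 4 (0.0766) or 100 µM replicates 3 (0.0567) or 4 (0.0976). Pank1, a pantothenate kinase (-0.74 ± 0.18, 0.0416), was not called within replicates 2 to 4 (0.0904), under median centring (0.12) or quantile normalization (0.113), nor without any single array except 100 µM replicate 2 (0.051 to 0.141). Zfhx3, a zinc-finger homeobox factor (-0.61 ± 0.15, 0.0483), was lost under median centring (0.19), quantile normalization (0.131) and without untreated replicates 2 (0.146), 3 (0.115) or 4 (0.13) or 100 µM replicates 1 (0.118), 2 (0.16) or 3 (0.106). The zinc-finger factor Zic1 (-0.61 ± 0.14, 0.0342) was lost within replicates 2 to 4 (0.0901), under median centring (0.0761), quantile normalization (0.0541) and without untreated replicates 1 (0.118) or 4 (0.114) or 100 µM replicates 1 (0.0867), 2 (0.121) or 4 (0.128).

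By list, p53 targets moved most at 100 µM. Of 26 measured p53 targets 14 rose and 0 fell (19 rises adjusted over the list alone, median 0.62, camera adjusted p = 5.83e-35, and 2.47e-06 with an estimated correlation), among them Plk2 (0.93 ± 0.09) and Psrc1 (1.05 ± 0.13). NRF2 targets, a list that includes genes of glutathione and thioredoxin metabolism, rose in 7 of 20 (13 adjusted over the list alone, median 0.33, camera adjusted p = 7.11e-23, and 4.12e-05 with an estimated correlation). Among the rises were the thioredoxin reductase Txnrd1 (0.80 ± 0.08) and the glutathione transferase Gsta4 (1.05 ± 0.12). ATF4 targets rose in 9 of 27 (16 adjusted over the list alone, median 0.30, 1.48e-22 and 2.47e-06), with Ddit3 (1.12 ± 0.10), Chac1 (1.13 ± 0.14) and Slc3a2 (0.63 ± 0.08). Immediate early genes rose in 6 of 31 (10 rises and 1 fall adjusted over the list alone, median 0.14, 1.35e-06 and 0.00257), with Myc (0.88 ± 0.12), Btg2 (1.19 ± 0.15) and Ier5 (0.59 ± 0.07). Short-lived zinc-finger and other repressors rose in 5 of 32 (7 adjusted over the list alone, median 0.06, 0.000629 and 0.00431), with Mafg (0.77 ± 0.13) and Nfil3 (0.70 ± 0.12).

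NF-kB targets and cytokines rose in 3 of 18 at 100 µM (5 rises and 1 fall adjusted over the list alone, median 0.30, camera adjusted p = 1.24e-05, and 0.00943 with an estimated correlation, 0.0666 with the replicate block added). The 3 were Ccl2, Nfkbia, the inhibitor of NF-kB (0.56 ± 0.11, adjusted p = 0.00692), and the cytokine Lif (0.74 ± 0.17, 0.034). The other probe set of Nfkbia differed from this one by -0.745 (limma adjusted p of the difference 0.485) and so did not rise. Lif was lost within replicates 2 to 4 (0.125) and without untreated replicates 1 (0.112), 2 (0.0611) or 3 (0.0923) or 100 µM replicates 1 (0.136) or 2 (0.122). The chemokine Cxcl1 stood at 2.10 ± 0.53 and was not called (0.0592), but was called without untreated replicate 1 (0.0351), within replicates 2 to 4 (0.037) and with the replicate block (0.0232). Further lists shifted upward without called members. These were heat shock proteins (0 of 23, 1 adjusted over the list alone, median 0.10, camera 0.00179, estimated correlation 0.00943, quantile normalization 0.0844), contractile genes (0 of 53; 0.14; 1.24e-05, 0.0465, and 0.304) and endoplasmic reticulum chaperones (0 of 20; 0.08; 0.0164, 0.0465, and 0.212), with 0 members of the latter lists adjusted over the list alone. With block and estimated correlation the adjusted p was 0.0992 for contractile and for reticulum genes. The latter's camera call ended without untreated replicates 1 (0.078) or 4 (0.0853) or 100 µM replicate 3 (0.0664).

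Other lists passed camera at 100 µM but not with an estimated correlation. Upward these were hypoxia targets (1 of 17, Ddit4, 0.82 ± 0.11, camera adjusted p = 0.00124; adjusted p = 0.0584 with an estimated correlation), proteasome subunits (0 of 31; 1.83e-06; 0.0527) and atrophy genes (0 of 14; 0.00179; 0.0653, and 0.019 with the replicate block). So were ribosomal proteins (0 of 33; 2.7e-06; 0.221), oxidative phosphorylation (0 of 56; 9.12e-05; 0.277), glycolysis (0 of 16; 0.0106; 0.188) and ribosome biogenesis (0 of 29; 0.0219; 0.46). Adjusted over the list alone, hypoxia had 1 rise and the others 0. Ddit4, the 1 called hypoxia target, is also on the p53 list. After quantile normalization ribosomal proteins (0.529), oxidative phosphorylation (0.736) and glycolysis (0.4) no longer passed camera. Ribosome biogenesis did not pass without untreated replicates 2 (0.0716), 3 (0.0501) or 4 (0.0853) or 100 µM replicate 1 (0.403). Downward these were cell cycle genes (1 of 39, Plk1, -0.44 ± 0.10, camera 0.00179; adjusted p = 0.185 with an estimated correlation), Notch targets (1 of 10, Hes1, -0.42 ± 0.09; 0.0124; 0.0803; 0.0535 without untreated replicate 3) and quiescent reserve cell markers (0 of 15, 2 adjusted over the list alone; 0.0395; 0.199). The reserve call ended without untreated replicates 2 (0.113), 3 (0.0966) or 4 (0.0632) or 100 µM replicate 1 (0.201). Plk1 and Hes1, each the 1 fall adjusted over its list alone, were fragile too. Plk1 was lost under median centring (0.118) and without untreated replicates 1 (0.0518), 3 (0.0553) or 4 (0.0766) or 100 µM replicates 2 (0.0695), 3 (0.0776) or 4 (0.0693). Hes1 was lost under median centring (0.0895) and without untreated replicates 2 (0.0777) or 4 (0.0632) or 100 µM replicates 2 (0.0646) or 3 (0.0709).

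The other lists were not called at 100 µM in the fit to all arrays. MAPK feedback genes fell in 1 of 12 (2 rises and 3 falls adjusted over the list alone, camera adjusted p = 0.107) and passed downward without 100 µM replicate 1 (0.00751) and under median centring (0.0426). Antioxidant enzymes (0 of 18; 0.132) passed upward without 100 µM replicate 1 (0.00403), as did fibroblast genes (0 of 22; 0.16) without that array (0.00154) or untreated replicate 2 (0.0372). Myogenic regulators (1 fall of 19; 0.304) passed without untreated replicate 1 (0.0297). Adipocyte, bone and cartilage genes (0 of 5; 0.111) passed without untreated replicate 1 (0.0336) or 100 µM replicate 3 (0.0442) and under median centring (0.0463). Metal-responsive genes (0 of 7; 0.121) passed with the replicate block (0.0172), but not with an estimated correlation (0.0696). Antioxidant enzymes (0.00658), metal-responsive genes (0.00357), MAPK feedback genes (0.0223) and myogenic regulators (0.033) passed camera within replicates 2 to 4, and endoplasmic reticulum chaperones did not (0.103). With an estimated correlation there, reticulum (0.242), NF-kB (0.105) and contractile lists (0.118) no longer passed, and antioxidant (0.0408), metal-responsive (0.0352), atrophy (0.0138) and hypoxia lists (0.0341) did, while MAPK feedback genes (0.0627) and myogenic regulators (0.0841) did not.

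In all, 175 probe sets were called at 100 µM, 124 up and 51 down, covering 94 and 46 genes, and 55 of them (50 up, 5 down) changed at least 1.75-fold. With the replicate block 402 were called (220 up, 182 down), all 175 among them, and within replicates 2 to 4 358 (195 up, 163 down), 152 of the 175 among them. Falls outnumbered rises in the fits with the batch term (279 up, 291 down) and with array weights (393 up, 490 down). Rises made up 70.9% of calls, 90.3% with median centring (168 up, 18 down) and 80.7% with centring on tested probe sets; 122 rises and 18 falls were called under trimmed-mean, median and quantile scaling alike. Without 100 µM replicate 2 the count was 116. The 4 arrays of each group separated fully in 1291 probe sets (8.98%, against 2.86% by chance).

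**Figure D2:**
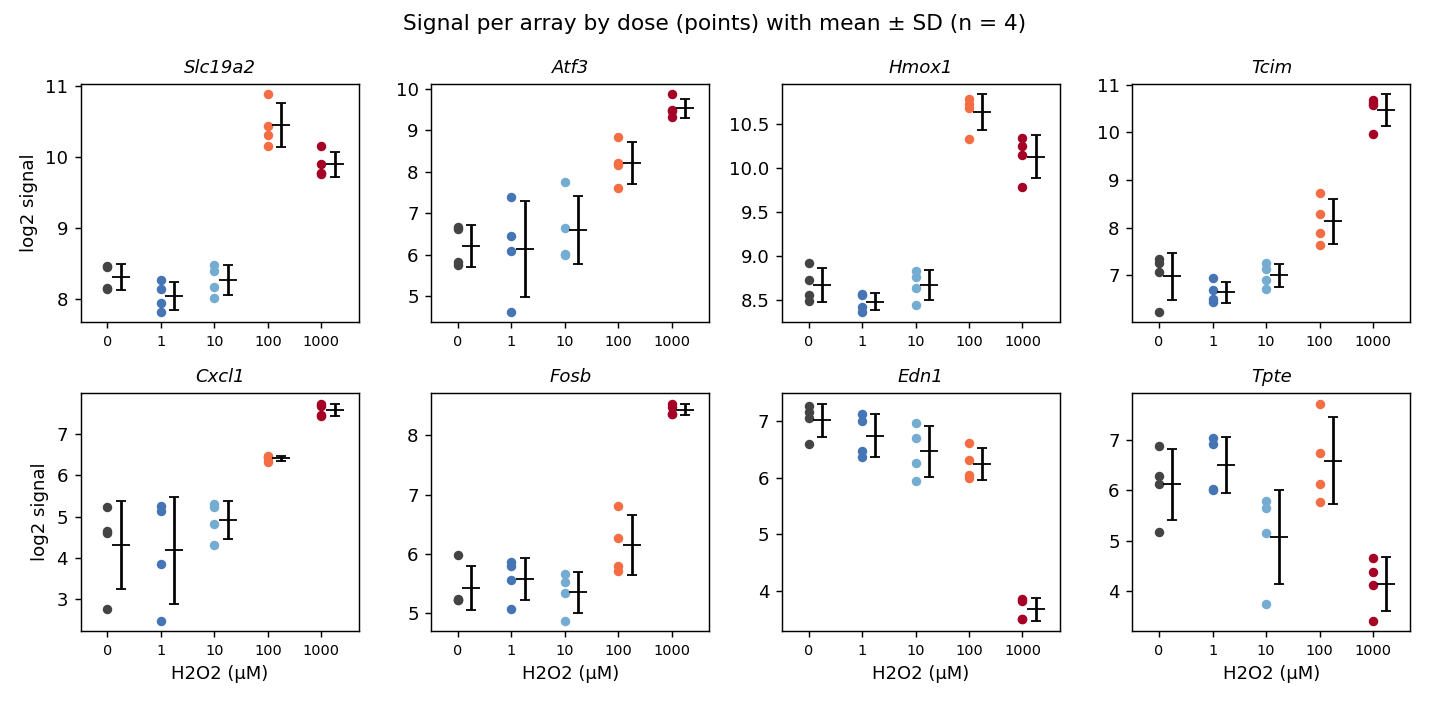
Log2 signal on each of the 20 arrays by H2O2 dose in µM for 8 genes chosen by size of change, with bars for group mean ± SD (n = 4). Slc19a2 rose by 2.15 at 100 µM, Tcim by 3.49 at 1000 µM, and Edn1 fell by 3.35 at 1000 µM.

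At 1000 µM the 12 largest rises included immediate early, chemokine and heat shock genes. Tcim, a small regulator of transcription, rose by 3.49 ± 0.24 (adjusted p = 4.87e-08), Atf3 by 3.31 ± 0.45 (5.27e-05), and the chemokine genes Cxcl1, Ccl2 and Ccl7 by 3.27 ± 0.53 (0.000457), 2.21 ± 0.22 (1.68e-06) and 2.01 ± 0.43 (0.00498). The AP-1 genes Fosb and Fos rose by 3.01 ± 0.27 (4.61e-07) and 2.02 ± 0.27 (4.7e-05), and the orphan nuclear receptor Nr4a1 by 1.99 ± 0.24 (1.41e-05). Hspa1a, the inducible Hsp70, rose by 2.19 ± 0.17 (8.48e-08) and its near-identical copy Hspa1b by 1.19 ± 0.15 (3.27e-05); their probe sets cannot be assumed to tell the copies apart. Noct, a clock-regulated gene, rose by 1.99 ± 0.20, Rnf225 by 2.27 ± 0.26 and Gzmm, a granzyme known from killer lymphocytes, by 2.63 ± 0.51. Cxcl1, Fosb, Gzmm, Rnf225 and Ccl7 lay under the filter level on all 4 untreated arrays, and Atf3 and Ccl2 on all but 1, so the sizes of these rises rest on dim signals. Leaving out any single array, or another scaling, ended 0 of these 12 calls.

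The largest falls at 1000 µM reached Edn1, the vasoactive peptide endothelin 1, which fell by 3.35 ± 0.27 (adjusted p = 1.18e-07) and lay under the filter level on all 4 arrays of that dose. The cyclins Ccnf and Ccnj fell by 1.59 ± 0.17 (4.08e-06) and 1.48 ± 0.25 (0.000685), the flippase Atp8b2 by 1.79 ± 0.33 (0.00134). Etaa1, an activator of the checkpoint kinase ATR, fell by 1.496 ± 0.25 (0.000675), Taf1c, a subunit of the RNA polymerase I factor SL1, by 1.40 ± 0.26 (0.00154). Lfng, a glycosyltransferase that modifies Notch, fell by 1.28 ± 0.23 (0.000957), and the zinc-finger genes Zfp574 and Zfp566 by 1.32 ± 0.15 (7.02e-06) and 1.29 ± 0.22 (0.000825). Tpte fell by 1.98 ± 0.49 (0.0135). Tpte, Etaa1, Ccnj, Thoc2l and Zfp566 also lay under the filter level on all 4 arrays of 1000 µM, and Taf1c and Lfng on all but 1. Zap70 (-1.76 ± 0.46, 0.0173) was not called without untreated replicate 1 (0.0575) or 1000 µM replicate 3 (0.0689). Thoc2l (-1.39 ± 0.41, 0.035) was lost within replicates 2 to 4 (0.0584), under median centring (0.0537), quantile normalization (0.083) and without untreated replicates 1 (0.0989), 2 (0.083) or 4 (0.058) or 1000 µM replicate 4 (0.103).

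Immediate early genes were the list with the most rises for its size at 1000 µM apart from NF-kB targets. Of 31 immediate early genes 12 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.31, camera adjusted p = 3.84e-12, and 0.000139 with an estimated correlation), with Myc (1.37 ± 0.12) and Jun (0.93 ± 0.09). Heat shock genes rose in 7 of 23 (10 rises and 1 fall adjusted over the list alone, median 0.21, 2.77e-09 and 0.000139), with the co-chaperones Dnajb1 (0.50 ± 0.09) and Dnajb4 (0.60 ± 0.12). NF-kB targets rose in 7 of 18 (7 rises and 1 fall adjusted over the list alone, median 0.18, 4.1e-05 and 0.0162, the latter 0.0793 with the block), with Nfkbia (1.10 ± 0.11) and Lif (1.04 ± 0.17). The other probe set of Nfkbia stood at 0.215 ± 0.203 and was not called (0.547), and the probe sets differed (limma adjusted p of the difference 0.0417). p53 targets rose in 9 of 26 (10 adjusted over the list alone, median 0.24, 1.02e-08 and 0.00372), with Plk2 (1.07 ± 0.09), Btg2 (1.49 ± 0.15), Psrc1 (1.22 ± 0.13) and Mdm2 (1.01 ± 0.13). ATF4 targets rose in 8 and fell in 1 of 27 (9 and 1 adjusted over the list alone, median 0.16, 4.64e-06 and 0.00372): Ppp1r15a, a phosphatase subunit that restores translation, rose by 1.10 ± 0.14 and Ddit3 by 0.58 ± 0.10, while Chac1, a glutathione-degrading enzyme, fell by 1.13 ± 0.14 (1.38e-05). Hypoxia targets rose in 5 of 17 (6 adjusted over the list alone, median 0.26, 6.98e-06 and 0.0162), with Adm, the vasodilator adrenomedullin (1.55 ± 0.28), and Higd1a (0.40 ± 0.07). NRF2 targets rose in 3 of 20 (4 adjusted over the list alone, median 0.16, 8.12e-05 and 0.033, the latter 0.0536 with the block): Hmox1 (1.45 ± 0.13), Osgin1 (1.28 ± 0.24) and Tkt (0.40 ± 0.13, 0.0479). Tkt was lost within replicates 2 to 4 (0.0667), with quantile normalization (0.0558) and without any single array but 1000 µM replicate 1 (0.0617 to 0.165).

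The Notch list, which holds receptors, ligands and a modifier besides targets, was the 1 list with a call downward at 1000 µM. Of 10, 5 fell (6 adjusted over the list alone, median -0.36, camera adjusted p = 0.00112, and 0.033 with an estimated correlation, 0.0536 with the block added), among them Lfng and the ligand Dll1 (-0.65 ± 0.12, 0.001). Hes1 (-0.36 ± 0.09, 0.0115) was lost under median (0.242) and quantile scaling (0.0778). Proteasome subunits rose in 3 of 31 (3 adjusted over the list alone, median 0.18, 1.02e-08 and 0.0298, the latter 0.0728 with the block, camera 0.125 after quantile normalization), with Psma6 (0.35 ± 0.08, 0.0111; 0.104 after quantile normalization). Endoplasmic reticulum chaperones passed upward (median 0.16, 0.0166 and 0.033, the latter 0.0959 with the block; 0.487 after quantile normalization, 0.0558 without untreated replicate 4), yet 0 of 20 rose and 2 fell (1 adjusted over the list alone). These 2 were the transcription factor Xbp1 (-0.31 ± 0.10, 0.049) and the ubiquitin ligase Syvn1 (-0.47 ± 0.13, 0.0256), neither called under median centring (0.58 and 0.164). Xbp1 was lost without any 1 of the 8 arrays (0.0536 to 0.135) and Syvn1 without untreated replicates 2 (0.0667), 3 (0.0608) or 4 (0.0569) or 1000 µM replicates 1 (0.0509), 2 (0.0506) or 3 (0.0651).

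Lists of abundant transcripts other than proteasome subunits passed camera upward at 1000 µM but not with an estimated correlation. Ribosomal proteins rose in 4 of 33 (12 adjusted over the list alone, median 0.29, camera adjusted p = 4.27e-11; adjusted p = 0.0891 with an estimated correlation), with Rps3 (0.43 ± 0.11, 0.0191; 0.211 after quantile normalization, 0.0519 without untreated replicate 1). Oxidative phosphorylation subunits rose in 8 of 56 (8 adjusted over the list alone; 0.17; 5.11e-11; 0.0813), with Cox5a (0.28 ± 0.07, 0.0184; 0.745 after quantile normalization, 0.0581 without untreated replicate 4, 0.0543 without 1000 µM replicate 3). Glycolysis rose in 3 of 16 (4 adjusted over the list alone; 0.17; 0.00112; 0.0891), with the glucose transporter Slc2a1 (0.47 ± 0.14, 0.0333). Slc2a1 was lost without untreated replicates 2 (0.102), 3 (0.0613) or 4 (0.068) or 1000 µM replicates 1 (0.101), 2 (0.0568) or 4 (0.0509). Antioxidant enzymes rose in 1 of 18 (1 adjusted over the list alone; 0.20; 0.0011; 0.18, and 0.0159 with the replicate block): catalase, Cat (0.29 ± 0.08, 0.0309; lost without untreated replicates 1, 0.0776, or 3, 0.0851, or 1000 µM replicates 1, 0.0745, or 2, 0.0959). After quantile normalization none of these 4 lists passed camera (0.207, 0.487, 0.473 and 0.0517). Contractile genes passed upward (median 0.06, 0.0316; adjusted p = 0.3 with an estimated correlation) but turned downward after quantile normalization (median -0.07, 0.00711). They did not pass under median centring (0.0704) or without untreated replicate 4 (0.152) or 1000 µM replicates 1 (0.0663) or 3 (0.061). They had 1 rise and 4 falls among 53 (the same counts adjusted over the list alone), such as Myom2 (-0.32 ± 0.07, 0.00729; 0.355 under median centring).

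The remaining lists were not called at 1000 µM. Myogenic regulators fell in 3 of 19 (1 rise and 4 falls adjusted over the list alone, camera adjusted p = 0.0688; 0.0313 with the block, though 0.0911 with an estimated correlation; 0.00249 after quantile normalization, 0.00688 without untreated replicate 1 and 0.0363 without 1000 µM replicate 4), with Myod1 (-0.51 ± 0.10, 0.00344; 0.0891 under median centring). Short-lived repressors rose in 5 and fell in 4 of 32 (9 and 4 adjusted over the list alone; 0.0623, and 0.0465 without untreated replicate 1), with Zfp36, which destabilises cytokine mRNA, up by 0.75 ± 0.09 and Klf2 at -0.72 ± 0.14. The test pointed up, the median was -0.03, and with median centring it turned to 0.17. Cell cycle genes rose in 5 and fell in 2 of 39 (6 and 2 adjusted over the list alone; 0.109; 0.0441 without untreated replicate 1 and 0.0238 without 1000 µM replicate 2), with Cks2 (0.36 ± 0.08) and Cdc25a (-0.76 ± 0.14). MAPK feedback genes rose in 2 and fell in 2 of 12 (the same adjusted over the list alone; 0.775), with Dusp1 (0.55 ± 0.15; 0.0502 without 1000 µM replicate 1) and Spry1 (-0.86 ± 0.10). SOCS and STAT genes fell in 2 of 10 (1 rise and 2 falls adjusted over the list alone; 0.834). Atrophy genes rose in 1 and fell in 2 of 14 (the same adjusted over the list alone; 0.834), with Foxo1 at -0.82 ± 0.12. Reserve cell markers fell in 2 of 15 (3 adjusted over the list alone; 0.363), with Rbl2 (-0.49 ± 0.09). TGF-beta and BMP targets rose in 2 of 13 (0.226), fibroblast genes in 1 of 22 (0.0554; 0.0188 with the block, but 0.393 with an estimated correlation). DNA repair (24; 0.634) and apoptosis genes (23; 0.363) each had 1 rise and 1 fall and cholesterol synthesis 1 fall of 16 (0.912), all with the same counts adjusted over the list alone. Fibroblast genes passed without untreated replicates 2 (0.0119), 3 (0.0144) or 4 (0.0482) or 1000 µM replicate 1 (0.00869). Ribosome biogenesis (0 of 29; 0.0615) passed without untreated replicate 1 (0.00852) or 1000 µM replicates 2 (0.0191), 3 (0.0217) or 4 (0.0141). Metal-responsive (7; 0.625), histone (6; 0.444) and adipocyte, bone and cartilage genes (5; 0.834) had 0 calls, as had the 4 measured leukocyte markers, too few to test (median -0.10).

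Within replicates 2 to 4 and with an estimated correlation, the calls at 1000 µM of NF-kB targets (adjusted p = 0.179), endoplasmic reticulum chaperones (0.179), Notch targets (0.0697) and proteasome subunits (0.0697) ended and antioxidant enzymes passed (0.00759). By camera, contractile genes no longer passed there (0.0505) and myogenic regulators did (0.0165; 0.0697 with an estimated correlation).

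In all, 1574 probe sets were called at 1000 µM, 354 up and 1220 down (265 and 916 genes), 259 of them (66 up, 193 down) with at least 1.75-fold. Which direction prevailed depended on the scaling. The median change over all tested probe sets was -0.07 as scaled and 0.13 with median centring. The share of rises went from 22.5% to 83.3% with median centring (2028 up, 407 down), 38.1% with quantile normalization (294 up, 477 down) and 66.3% with centring on tested probe sets (1155 up, 588 down). Called under trimmed-mean, median and quantile scaling alike were 189 rises and 324 falls (149 and 261 genes). With the replicate block 2854 probe sets were called, the 1574 among them, and within replicates 2 to 4 2528 (697 up, 1831 down), 1353 of the 1574 among them. Without 1000 µM replicate 2, 3 or 4 the count was 990, 1033 or 1049. Groups separated fully in 2945 probe sets (20.5%, against 2.86% by chance).

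**Figure D3:**
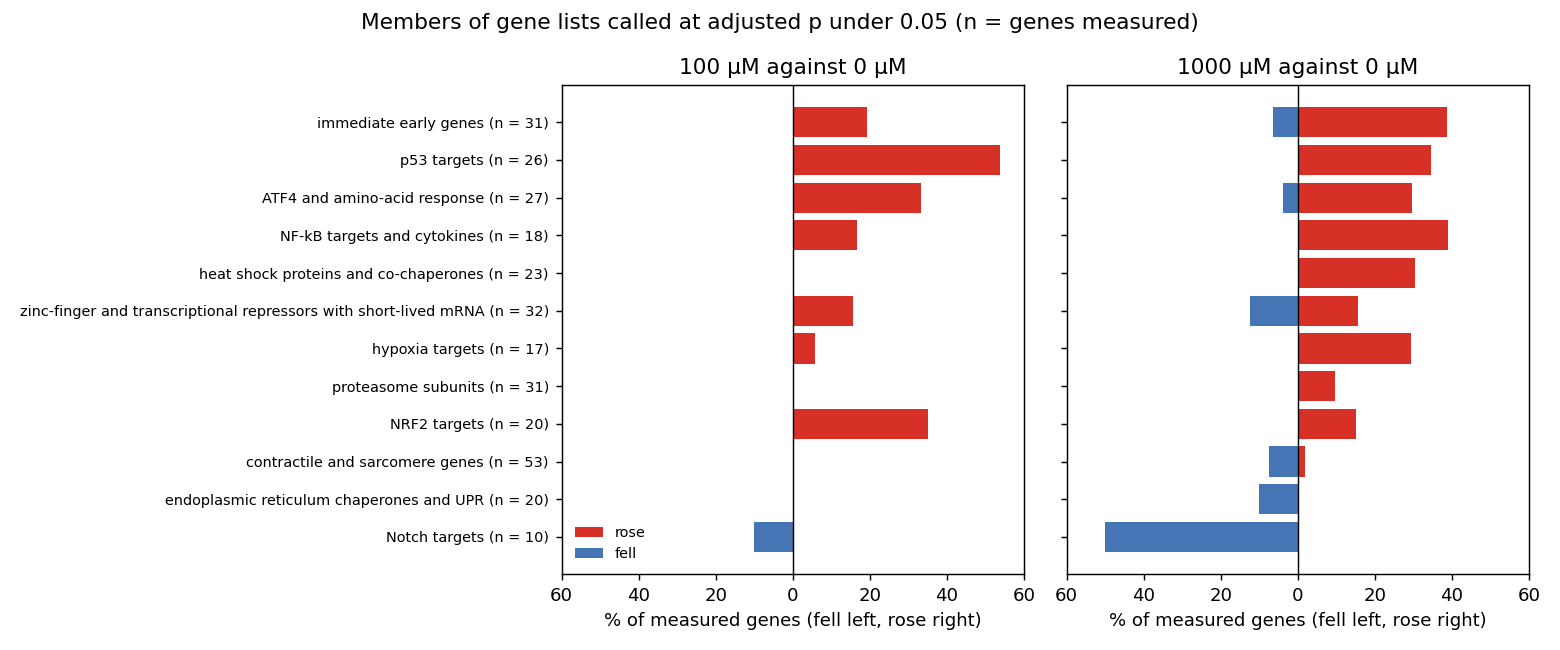
Percent of measured members called at 100 and at 1000 µM, rises right and falls left of 0, for the gene lists that passed with an estimated correlation at either dose. p53 targets had 14 rises of 26 at 100 µM and 9 at 1000 µM, endoplasmic reticulum chaperones had 2 falls at 1000 µM although their list test pointed up, contractile genes pointed up there but down after quantile normalization, and the median of short-lived repressors, -0.03, turned to 0.17 with median centring.

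Direct comparison of 1000 with 100 µM placed the immediate early and heat shock lists higher, and the NRF2 list lower, at the higher dose. Tcim (2.34 ± 0.24, adjusted p = 7.05e-06), Fosb (2.28 ± 0.27), Hspa1a (1.97 ± 0.17), Fos (1.97 ± 0.27), Noct (1.496 ± 0.20), Hspa1b (1.47 ± 0.15), Adm (1.43 ± 0.28), Gt(ROSA)26Sor (1.01 ± 0.13) and Jun (0.84 ± 0.09) were higher at 1000 µM. So were Rnf225 (1.00 ± 0.26, 0.0288), Nr4a1 (0.95 ± 0.24, 0.0252) and Hbegf, a growth factor of the EGF family (0.87 ± 0.24, 0.0415), with less support. Lower were Edn1 (-2.58 ± 0.27), Tpte (-2.45 ± 0.49), Chac1 (-2.26 ± 0.14, 3.39e-09), Foxq1 (-1.87 ± 0.23), Ccnf (-1.36 ± 0.17), and Uhrf1bp1 (-1.34 ± 0.16). So were Etaa1 (-1.28 ± 0.25), Taf1c (-1.25 ± 0.26), Zfp566 (-1.24 ± 0.22), Fam83h (-1.20 ± 0.23), Zfp113 (-1.18 ± 0.26) and Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis (-1.18 ± 0.16, 9.98e-05). Rnf225 was lost after quantile normalization (0.0652) and without 100 µM replicates 2 (0.0705) or 4 (0.105) or 1000 µM replicates 1 (0.0854), 2 (0.0734) or 3 (0.0695). Nr4a1 was lost without 100 µM replicates 2 (0.0703), 3 (0.0718) or 4 (0.0921) or 1000 µM replicates 2 (0.0791), 3 (0.0641) or 4 (0.0661). Hbegf was lost after quantile normalization (0.0663) and without any single array except 100 µM replicate 1 (0.0581 to 0.128).

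Of 20 NRF2 targets, 7 were lower and 1 higher at 1000 than at 100 µM (12 and 1 adjusted over the list alone, median -0.35, camera adjusted p = 7.54e-06, and 0.0283 with an estimated correlation), including Srxn1 (-1.13 ± 0.16), Gsta4 (-0.78 ± 0.12), Txnrd1 (-0.59 ± 0.08) and Hmox1 (-0.50 ± 0.13). p53 targets were lower in 7 of 26 (9 adjusted over the list alone; -0.22; 1.45e-05 and 0.0283, the latter 0.0644 with the block), including Sesn2 (-0.77 ± 0.21), Trp53inp1 (-0.76 ± 0.13) and Ddit4 (-0.75 ± 0.11). ATF4 targets were lower in 6 of 27 (8 lower and 1 higher adjusted over the list alone, median -0.10, 0.02 with median centring; 0.00768; adjusted p = 0.0705 with an estimated correlation). Higher were immediate early genes (9 of 31, with 2 lower, and 12 and 4 adjusted over the list alone, camera adjusted p = 3.87e-06, and 0.00462 with an estimated correlation). Heat shock genes were higher too (3 of 23, the same adjusted over the list alone, camera adjusted p = 0.00462 with an estimated correlation). These 3 include Hspa1a and its near-identical copy Hspa1b, so few separate genes carry the calls. Cell cycle genes also were (4 of 39, with 1 lower; 7 and 1 adjusted over the list alone; 7.09e-06; adjusted p = 0.0705 with an estimated correlation). Altogether 13 lists passed camera and 4 with an estimated correlation. Atrophy genes, lower by camera (0.0422; adjusted p = 0.308 with an estimated correlation), did not pass with the block (0.0818) or within replicates 2 to 4 (0.152). Antioxidant enzymes moved the other way from NRF2 targets, upward by camera (0 of 18 called; median 0.12, 0.018, and 0.00228 with the block; adjusted p = 0.371 and 0.0644 with an estimated correlation). ATF4 targets passed with an estimated correlation within replicates 2 to 4 (0.0456), and glycolysis passed camera alone there (0.0191; 0.351 with an estimated correlation). The comparison called 625 probe sets, 107 higher and 518 lower at 1000 µM (86 and 424 genes), and 1390 with the replicate block, all 625 among them. Rises were 17.1% of calls, 52% with median centring (208 up, 192 down) and 28.5% with quantile normalization (105 up, 263 down), with medians over all tested probe sets of -0.04 as scaled and 0.09 with median centring. The count was 361 without 100 µM replicate 4 and 408, 374, 415 and 374 without 100 µM replicate 2 and 1000 µM replicates 2, 3 and 4.

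Between 10 and 100 µM 134 probe sets changed, 111 up and 23 down (82 and 20 genes; 206 with the replicate block, 121 of the 134 among them; 298 within replicates 2 to 4, 124 among them). Of p53 targets 13 of 26 were higher at 100 µM (20 adjusted over the list alone, camera adjusted p = 4.72e-44, and 8.01e-07 with an estimated correlation). So were 8 of 20 NRF2 targets (11 adjusted over the list alone; 4.88e-05 with an estimated correlation), 7 of 27 ATF4 targets (9 adjusted over the list alone; 4.81e-06) and 6 of 31 immediate early genes (12 and 1 lower adjusted over the list alone; 6.16e-05). NF-kB targets (3 of 18; 0.00166), short-lived repressors (5 of 32; 0.000117) and hypoxia targets (1 of 17; 0.0454) also passed upward with an estimated correlation. Cell cycle genes passed downward (1 of 39 lower, 15 adjusted over the list alone, median -0.21, 0.00255), as did cholesterol synthesis (0 of 16; median -0.14, 0.0158). Atrophy genes passed camera alone (0.0477; adjusted p = 0.292 with an estimated correlation) and did not within replicates 2 to 4 (0.0648) or with the replicate block (0.0801), where reserve cell markers passed (0.0354, against 0.24; 0.0877 with an estimated correlation).

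Over dose rank, 1612 probe sets were called for the weighted trend, 405 up and 1207 down, and 2884 with the block, the 1612 among them. Rises were 25.1% of calls, against 80.1% with median centring, 62.7% with centring on tested probe sets and 45% with quantile normalization. A change at 1000 µM alone can also pass this contrast. Against 0 µM, 0, 1, 175 and 1574 probe sets were called at 1, 10, 100 and 1000 µM. A trend call therefore does not show that a gene changed step by step with dose. The largest rank-weighted sums were those of Cxcl1 (8.76 ± 1.19), Atf3 (8.69 ± 0.99), Tcim (8.47 ± 0.54), Gzmm (7.47 ± 1.15) and Fosb (6.59 ± 0.61) upward. Downward they were those of Edn1 (-7.20 ± 0.60), Zap70 (-4.81 ± 1.02), Atp8b2 (-4.36 ± 0.73), Tpte (-3.86 ± 1.10) and Ccnf (-3.60 ± 0.38). These sums are not changes per step. Cxcl1, Gzmm and Fosb lay under the filter level on every untreated array and Atf3 on most of them. Edn1 and Tpte lay under it on every array of 1000 µM, so the sums and ranks of these genes are inexact. By list, 16 had a trend by camera and 11 with an estimated correlation. With the block added to the latter, endoplasmic reticulum chaperones (adjusted p = 0.0268, then 0.0913) and proteasome subunits (0.0279, then 0.0838) no longer passed, antioxidant enzymes did (0.243, then 0.0184), and myogenic regulators passed camera (0.0928, then 0.0377; 0.0924 with an estimated correlation). Within replicates 2 to 4 endoplasmic reticulum (0.156), proteasome (0.0622), NF-kB (0.0852) and Notch lists (0.0693) no longer passed with an estimated correlation, antioxidant enzymes did (0.0102), and myogenic regulators (0.0301) and reserve cell markers (0.0398) passed camera alone (0.0852 for both with an estimated correlation). Tpte's trend was lost without untreated replicates 1 (0.076), 2 (0.0536) or 3 (0.0528) or 1000 µM replicates 3 (0.0766) or 4 (0.053). The F-test over all 5 doses called 1152 probe sets, 2271 with the block, and 674, 735 and 692 without 1000 µM replicates 2, 3 and 4.

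Changes at 100 and 1000 µM shared 66 rises, against 3.05 for independent lists of the same sizes, and 32 falls, against 4.33. Only 1 probe set rose at 100 and fell at 1000 µM (10.52 for independent lists) and 0 did the reverse (1.26). Both comparisons use the same untreated arrays, so the lists are not independent. Shared controls alone favour changes in the same direction, so the values for independent lists are no measure of what the doses share. Unchanged groups simulated against shared controls gave 0 shared calls, but with a mean of 0.05 calls at each dose they could hardly share any, so that 0 says little about the 66. Across tested probe sets, which are not independent replicates, the changes at both doses correlated with r = 0.549. The same controls alone gave a simulated r of 0.501, so a value near this one arises without any effect. The covariance was 0.0418 against a simulated 0.0208, a difference of 0.021. The simulated spread included the batch of arrays numbered 1, which cancels in the real comparisons, so the simulated covariance is likely too high. With controls split between the doses, r averaged 0.185 (0.137 to 0.248). Every split gave untreated replicate 1 to 1 dose alone. The batch then entered both changes with opposite sign, which lowers r, so this value does not measure what the doses share.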

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

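In this part the tests on the untreated replicate 1 array, on quantile normalization and on the excess of falls at 1000 µM were chosen only after the result was seen.

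A value is listed here when 1 array of 4 lay so far from the other 3 that the gap took up most of the group's range; the ratio of gap to range is given, and chance picks out about 1 in 20 groups. Of 35 groups of array measures 7 stood out. The first principal component parted the array numbered 1 from the rest in every group, at 1000 (ratio 0.998), 0 (0.967), 100 (0.914), 1 (0.878) and 10 µM (0.85). The highest signal of 10 µM replicate 4 was 20740, against 13260 to 14080 (0.89), and the median log2 signal of tested probe sets of 1000 µM replicate 3 was 8.664, against 8.68 to 8.683 (0.856).

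Of 275 groups of 55 named genes 15 stood out (5.45%), in 9 of them by the array numbered 1. That array was highest for Fosb at 0 µM (0.98), Mdm2 at 10 µM (0.972), Fos at 100 µM (0.894) and Hbegf at 100 (0.864) and 10 µM (0.863). It was lowest at 1000 µM for Ccl2 (0.889), Gzmm (0.866), Tcim (0.858) and Fam83h (0.85). Other single arrays were low for Zfp566 at 100 µM (replicate 3, 0.948), Uhrf1bp1 at 1 µM (replicate 2, 0.926), Trp53inp1 at 10 µM (replicate 4, 0.878), Ect2 at 10 µM (replicate 4, 0.847) and Thoc2l at 1000 µM (replicate 4, 0.842), and high for Gt(ROSA)26Sor at 1000 µM (replicate 2, 0.889).

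Members of the lists of abundant transcripts (ribosomal proteins, oxidative phosphorylation, proteasome and contractile genes, 173 members) lay higher at 1 µM (median 0.107) as well as at 10 (0.102), 100 (0.119) and 1000 µM (0.179). Without untreated replicate 1 the median at 1 µM was 0.056, which left open whether that array caused the shift. After quantile normalization it was 0.01, so different signal distributions left by trimmed-mean scaling could account for the shift, although that step would also remove a real rise of abundant transcripts. Within replicates 2 to 4 the median was 0.058 at 1 and 0.137 at 1000 µM, a difference of 0.079 (SE of the mean paired difference 0.012, over list members rather than arrays), so a response that grows with dose also stays open. After quantile normalization the mean difference there was 0.032 (SE 0.011), but over all arrays the median at 1000 µM was only 0.019, against the 0.01 at 1 µM.

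More falls than rises were called at 1000 µM. Rises made up 22.5% of calls as scaled, 83.3% after median centring and 38.1% after quantile normalization, so an effect of scaling cannot be told apart from a real excess of falls, because the scalings gave different answers. Degraded RNA stayed open too: the larger difference in 3' to 5' ratio was 0.0627, but its upper bound of 0.206 took in the 0.2 set for it. As scaled, noise of dim probe sets as the whole cause was argued against, since rises made up 35.1% (upper bound 38.6) of the 780 calls above the median brightness. That bound treats probe sets as independent, although they share arrays and some share a gene, so it is likely too narrow. The argument does not carry over to median centring, under which rises prevailed among the brighter probe sets. Yet the excess followed brightness: of 4 equal bins the next to brightest had 63 rises and 376 falls, the brightest 211 and 130 (1351 and 24 with median centring), and a real excess of falls was not tested separately.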

How the results depend on the processing

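The fits to replicates 2 to 4, with the batch term and with centring on tested probe sets were chosen only after the result was seen. Of the planned and added settings other than left-out arrays, the count stayed within 1.5 times in 12 of 16 at 1 µM, 7 of 16 at 10 µM, 9 of 16 at 100 µM, 8 of 16 at 1000 µM, 14 of 14 for 10 against 1 µM, 10 of 14 for 100 against 10 µM, 8 of 14 for 1000 against 100 µM, 8 of 13 for the trend and 9 of 13 for the F-test. It did for lists in 14, 13, 16 and 17 of 17 at 1, 10, 100 and 1000 µM.

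Counts that moved are given in the order 1, 10, 100 and 1000 µM, 100 against 10, 1000 against 100 µM, trend and F-test (0, 1, 175, 1574, 134, 625, 1612 and 1152 in the report). With array weights they were 49, 79, 883, 4267, 762, 2655, 4235 and 4767, within replicates 2 to 4 107, 4, 358, 2528, 298, 1302, 3051 and 2925, and with the batch term 16, 2, 570, 3282, 353, 1658, 3317 and 3003. With the replicate block, from 10 µM on, they were 2, 402, 2854, 206, 1390, 2884 and 2271; the block ended 0 and added 32 calls of named genes and changed no list call other than those given beside a result. Median centring gave 0 at 10 µM, 2435 at 1000 µM and 400 for 1000 against 100 µM, centring on tested probe sets 0 at 10 µM, and quantile normalization 771 at 1000 µM, 368 for 1000 against 100 µM and 962 for the trend. Only the 2 groups compared gave 0 and 98 at 10 and 100 µM, a minimum of 1.75-fold 0, 55 and 259 at 10, 100 and 1000 µM, and the crossed rule 11, 17, 81 and 265. Lists moved at 1, 10 and 100 µM numbered 0, 0 and 9 with an estimated correlation (8, 9 and 19 in the report), and at 1 and 10 µM 0 and 0 with fry and 2 and 2 after quantile normalization; with the mean of probe sets 5 moved at 10 µM. The correlation of 0.549 was 0.513 without a filter and 0.185 with split controls. Aldoa at 1000 µM turned from 0.28 to -0.012 (adjusted p = 0.94) after quantile normalization. For all of these the cause was not tested.

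Leaving out 1 array gave 0 to 1 probe sets at 1 µM, 0 to 1 at 10 µM, 116 to 172 at 100 µM, 990 to 1358 at 1000 µM, 361 to 524 for 1000 against 100 µM and 674 to 1477 for the F-test, 5 to 10 lists at 1 µM and at 10 µM, and a correlation of 0.51 to 0.611. Of 318 results for named genes, 176 of them called, median centring ended 27 calls and added 26, quantile normalization ended 36 and added 6, and leaving out 1 array ended 268 and added 11 of 2664. Only the 2 groups compared ended 42 of 166 calls and added 4, no filter ended 18 and added 0, and replicates 2 to 4 alone ended 16 and added 20. The 40th-percentile filter limits what dim probe sets can show.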

Other observations

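The regroupings of arrays for probe-set counts of single doses and of neighbouring doses were chosen only after the result was seen. So were the tests of compressed probe-set responses and of opposite calls under other settings. The count of genes whose pairs all hold a probe set open to cross-hybridisation or shared transcripts was too. The gene families and probe-set pairs named here were also chosen then.

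Genes of 1 family fell together at 1000 µM. Of 116 measured genes whose symbols begin with Zfp, mostly zinc-finger proteins, 37 fell (31.9%), against 657 of all 8159 genes (8.1%, each gene by its brightest probe set alone; exact test, p = 7.77e-14; adjusted p = 6.37e-12 over 41 families, each tested for rises and for falls; median -0.35). Among them were Zfp574 and Zfp566. With median centring 23 Zfp genes fell (exact test, p = 4.95e-15) and with quantile normalization 21 (exact test, p = 2.18e-10). As scaled no other family passed, the next being Usp, ubiquitin-specific proteases, with 8 falls of 31 (adjusted p = 0.103). With median centring, under which 1270 of the 8159 genes rose, families of abundant transcripts rose, such as Rps with 17 of 23 (exact test, p = 6.65e-10), Eif with 23 of 41 (exact test, p = 2.58e-09) and Rpl with 14 of 22 (exact test, p = 4.27e-07). After quantile normalization these families had 1, 0 and 0 rises (exact tests, p = 0.415, 1 and 1). Genes of a family are not independent, since related probe sequences can bind the same transcripts.

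Probe sets of 1 gene moved apart at 1000 µM in 43 of 3300 genes. Pabpn1, the nuclear poly(A)-binding protein, had probe sets at -1.80 and 0.74 (adjusted p of the difference 2.96e-08), Fn1, fibronectin, at -2.05 and 0.16 (1.3e-07), Hnrnpdl at -0.67 and 0.36 (1.78e-07), Rbbp6 at 2.08 and -0.08 (3.95e-07), Nisch at -2.48 and -0.09 (1.71e-06), Hnrnpa2b1 at -1.11 and 0.24 (6.76e-06), Rps24 at -1.22 and 0.31 (2.66e-05) and the splicing factor Srsf3 at -0.91 and 0.30 (7.66e-05). The rising probe set of Rbbp6 was dim, with an untreated signal of 65.12, so the size of its rise is inexact. Of 226 genes with several called probe sets, 6 were called in opposite directions: Hnrnpa2b1, Hnrnpdl, Nisch, Pabpn1, Rps24 and Srsf3. For Nisch the upward call was that of another probe set, at 1.01 (limma adjusted p = 0.00104), with a dim untreated signal of 138. After quantile normalization 4 were left, without Hnrnpa2b1 and Rps24. Leaving out single arrays gave 3 to 5, median centring 11 and replicates 2 to 4 alone 13, always with Hnrnpdl, Nisch and Pabpn1. The genes with unequal probe sets numbered 87 within replicates 2 to 4, 81 with the replicate block, 22 after quantile normalization, 25 without untreated replicate 2, 26 without untreated replicate 4 and 28 without 1000 µM replicate 2.

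Probe sets with names ending in _x_at, _s_at or _a_at were taken as open to cross-hybridisation or shared transcripts. This explanation was argued against for genes tested on other probe sets alone: 1.81% of them were called, against 1.3% of all. That test left out the pairs of 26 of the 43 genes, Pabpn1, Hnrnpdl and Nisch among them, for which this explanation stays open. The brightest probe sets of Pabpn1, Hnrnpdl and Nisch end in _a_at. The test did not separate the endings, so cross-hybridisation by itself was not tested for them. Compression of the brighter or dimmer probe set was argued against for 3 genes, Hnrnpdl, Nisch and Pabpn1. Their probe sets were called in opposite directions under trimmed-mean, median and quantile scaling, within replicates 2 to 4 and without any single untreated or 1000 µM array. For the others it stayed open: 39.5% of the 43 genes (upper bound 55.6) had all probe sets moving 1 way, and of 5 with the brightest probe set and another called in opposite directions only 1 was left after quantile normalization. Use of other transcript ends could likewise give such pairs; it was not tested.

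Other splits of the arrays were counted, the real one included. At 10 µM 2 of 35 splits called as many probe sets (real 1, highest other 1), so chance cannot be excluded there. At 1 µM and for 10 against 1 µM all 35 did, as the real count of 0 makes certain (highest other 0 in both), so the splits decide nothing. Only the real split reached the count for 100 µM (175, highest other 2), 1000 µM (1574 and 0), 100 against 10 µM (134 and 1) and 1000 against 100 µM (625 and 0). That share is under 0.05 and the smallest that 35 splits can give. Some of the other splits put both arrays numbered 1 in 1 group, so chance is made less likely there but not excluded. Of the 8 splits that part all 4 replicate numbers, no other called a probe set in any comparison, though 8 splits are too few for a share under 0.05. For the F-test 1 of 100 groupings, the real one, reached 1152 (highest other 1), a share under 0.05. For the trend 2 of 100 groupings reached 1612; the larger, 1927, placed the 5 arrays numbered 1 mostly at high ranks (mean rank weight 1.6, against 0 in the real order), so it follows that batch, and within replicates 2 to 4 the real order called 3051.

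For lists moved, chance cannot be excluded at 10 µM (4 of 35 splits; real 9, highest other 9) or 1000 µM (7; 15 and 18). At 1 µM 1 split reached the real 8, but another reached 7 and the count was 5 without 1 µM replicate 1, 2 after quantile normalization and 0 with an estimated correlation. At 100 µM 1 split reached the real 19, but another reached 16, as did the real one without untreated replicate 3, and the count was 9 with an estimated correlation. Chance is therefore not taken as excluded at either dose. Among splits that part all 4 numbers the highest others were 7, 9, 14 and 18 at 1, 10, 100 and 1000 µM. For genes whose probe sets moved apart, 1 of 35 splits, the real one, reached the 43 at 1000 µM (highest other 1), again a share under 0.05. At 1 µM 4 splits reached the real 1 (highest other 4), so chance cannot be excluded there. At 100 µM 1 split reached the real 2 (highest other 1). Yet 0 were left after quantile normalization and 1 without the probe sets open to cross-hybridisation or shared transcripts, so little rests on it. At 10 µM the real count of 0 was reached by all 35 (highest other 1), which decides nothing.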
